A study of Mus musculus with 6 samples.

How the data were processed

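Total RNA (15 ug per sample, per the labels' protocols) from 3 cultures of parental E0771 cells and 3 cultures of E0771-HML2 cells was labelled with biotin and hybridised to Affymetrix GeneChip Mouse Genome 430 2.0 arrays, with 1 array per culture. The cells had been grown for 3 days in medium with 10% fetal bovine serum. The labels give replicate numbers 1 to 3 in each group and call them biological replicates; they do not say whether the 3 HML2 cultures came from different animals, so p-values measure the spread between these cultures. The deposited values are linear intensities, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes. The version and settings are not given in the sources used here. MAS5 summarises the probe pairs of a probe set into a signal, and the deposited table had been scaled: the mean after leaving out the lowest and highest 2% of signals was 500 on all 6 arrays. Such scaling removes any difference in total messenger RNA between the cell populations, and the unlogged low signals are noisy, which is why an offset and a signal filter were used. The table held no detection calls. Bacterial tryptophan control probe sets, which should not hybridise to mouse RNA, had signals of 1.97 to 36.2 with a median of 11.3 and served as a gauge of background.

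The table held 45101 probe sets, of which 64 were controls. The array annotation, dated 2016, gave 1 gene symbol for 34945 probe sets and several for 932, and 9160 were not listed in it. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6, in which 34741 of the probe sets with 1 symbol were found. That table was used for names and for which genes share a chromosome. No genome build was named for the array values, so no coordinates are given, and chromosomes are described by genes they carry. Genes were named from probe sets with 1 symbol.

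Signals were converted to log2(signal + 50). Probe sets with a mean signal of at least 100 over all 6 arrays were kept, and the probe set with the highest mean log2 value represented each gene, which left 9361 genes. Differences are HML2 minus parental on this scale and understate the change of genes with low signals. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) without covariates, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05. Of the called genes, 1231 had several probe sets that passed the filter. In 227 of these another probe set had the opposite sign, and in 40 another probe set was called in the opposite direction.

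A total of 37 gene lists was fixed from general knowledge before the data were examined, together with the tests, the alternatives and the rule for naming genes. The 33 lists with at least 5 tested members were compared with all other tested genes by camera with its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated for each list. With an estimated correlation no list was called, and the lowest adjusted p was 0.37. Lists overlap: Cxcl1, Acta2, Thbs1, Col3a1, Mmp2 and Egfr, for example, each stand in more than 1 list. Genes were named by a rule with 3 parts. The first took the 12 called genes with the largest increase and the 12 with the largest decrease among those whose groups did not overlap and whose brighter group had a mean signal of at least 250. The second took, for each list, up to 4 called members with the largest differences, filled up to 2 by the brightest members. The third took the 3 brightest members of the lists of other cell types and of sex-chromosome genes. Some genes outside this rule were named after their values were seen, to complete small counts or to show members that did not change: Ptges, Nfkbia, Nfkbie, Tnfaip3, Relb, Nfkb2, Ccl2, Il18, Il6, Dnajb9, Pdia6, Dnajc3, Nid1, Lama5, Lamb1, Junb, Tgfbr1, Tgfbr2, Tgfb1, Prrx1, Twist2, Vim, Zeb1, Zeb2, Snai2, Twist1, Nlrc5, Psmb10, Psme1, H2-K1, H2-D1, B2m, Epcam, Tff1, Nsdhl, Lyz2, Ptprc, Sftpb and Icam2. Of the genes the rule selects, 1 is not reported here. No gene chosen by the first part lacked a regular symbol.

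RNA integrity was assessed by the ratio of 3' to 5' control probe sets of Gapdh and beta-actin, with exact two-sided permutation tests, for which 3 against 3 arrays allow no p below 0.1. Whether replicate numbers pair the arrays was checked by correlating, across genes, the deviations of arrays from their group means. Arrays with the same number had correlations of 0.45, 0.34 and 0.24, all above the bound of 0.1 used here. The labels do not name what the number stands for. The main fit did not use the number, which entered as a block in an alternative. Calls in the report are therefore unpaired unless the block is named. Parental replicate 2 and HML2 replicate 3, which do not share a number, also had a correlation of 0.24. The number thus does not single out a partner for HML2 replicate 3. Replicate 1 of each group had negative correlations with the arrays of other numbers in the other group, from -0.38 to -0.19.

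Alternatives covered the offset (none, or 200), raising signals under 50 to 50, the signal filter (none, or a mean of 250), quantile normalization and median centring, limma without trend, with a robust variance and with array weights, the treatment of several probe sets per gene, the replicate number as a block, and leaving out each array. The fitting procedure was tested on data simulated for this comparison (9361 genes, 200 changed, 5 runs). It recovered 70.4% of genes changed 2-fold and 94.8% of those changed 4-fold, 3.82% of its calls were false, and camera called 5 of 5 shifted and 0 of 100 unshifted lists. The simulated arrays had no correlation between genes, so this does not test the preset correlation. All 25 members of a shifted list were raised 2- or 4-fold, so its call was nearly given. Far fewer genes were changed than the 2550 called in the data, so these rates need not hold there.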

Results

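Messenger RNA was measured in E0771 cells, a mouse mammary tumour line of the C57BL/6 strain, and in a derivative named E0771-HML2. The derivative is a second-generation population: cells placed in the mammary fat pad of syngeneic mice were recovered from the lung, and the passage through the animal was repeated. Unselected parental cells and HML2 cells were each represented by 3 cultures, described in the labels as biological replicates, and each culture was hybridised to its own oligonucleotide array. The cells had been grown for 3 days in medium with serum, so all values describe cells in culture and not tumours or lungs. The deposited signals were scaled to a common trimmed mean of 500 on all 6 arrays, and 39.7% to 41.6% of probe sets reached a signal of 100. Of 18193 genes represented by probe sets with 1 gene symbol, 9361 passed the signal filter and were tested. The number of arrays limits the precision of every value.

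The comparison asks how the metastasis-selected population differs in expression from the cells it came from. The largest increases in HML2 cells included chemokine genes, and the largest decreases included collagen genes. Cxcl1, a neutrophil-attracting chemokine, had a mean signal of 675 ± 311 in parental and 23029 ± 8542 in HML2 cells (SD, n = 3), a log2 difference of 5.02 ± 0.32 (SE). Lcn2, an iron-siderophore-binding secreted protein, went from 7.90 ± 3.21 to 2441 ± 2709, and the chemokine Cxcl2 from 27.6 ± 9.12 to 1462 ± 1429. HML2 replicate 1 carried much of both means, with signals of 5562 for Lcn2 and 3110 for Cxcl2 against 711 and 1049 and against 578 and 696 on the other HML2 arrays. In the opposite direction, the fibrillar collagen gene Col3a1 went from 22628 ± 2298 in parental to 602 ± 217 in HML2 cells, a log2 difference of -5.18 ± 0.24. The smooth muscle actin gene Acta2 went from 15281 ± 6332 to 482 ± 282, and the growth factor gene Ptn from 8539 ± 1204 to 369 ± 79.2.

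In all, 1155 genes were higher and 1395 lower in HML2 cells (limma, Benjamini-Hochberg adjusted p below 0.05), together 27.2% of the genes tested. A difference of at least 2-fold was reached by 270 of the higher and 502 of the lower genes. The 3 HML2 arrays lay entirely on one side of the 3 parental arrays for 4155 genes, whereas chance gives 10% of genes. These counts changed with the processing and with the arrays used. The main fit did not use the replicate number, and with that number as a block there were 1670 higher and 1831 lower genes. Array weights gave 2422 higher and 2631 lower genes, and median centring gave 1357 and 1178, with more genes higher than lower. Without parental replicate 3 there were 590 higher and 795 lower genes, and without HML2 replicate 3 there were 715 higher genes.

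**Figure D1:**
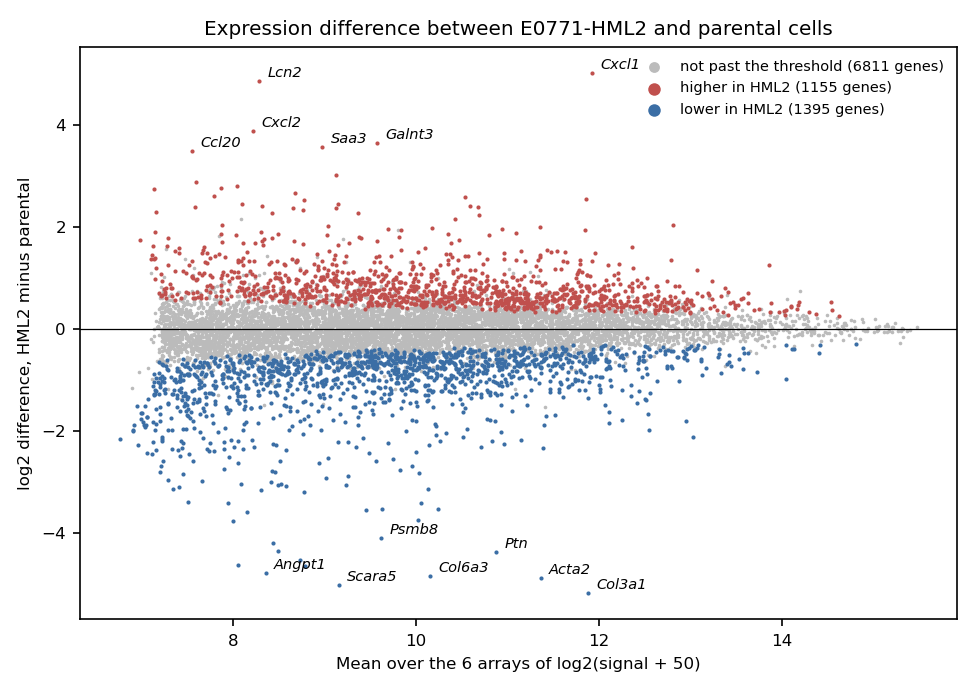
Each point is 1 of 9361 genes, with the mean of log2(signal + 50) over the 6 arrays on the horizontal axis and the log2 difference, HML2 minus parental, on the vertical axis. Red points are the 1155 genes higher and blue points the 1395 genes lower in HML2 cells, and the labelled extremes include Cxcl1 at 5.02 and Col3a1 at -5.18.

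The 12 genes with the largest increases were, after Cxcl1, Lcn2 (4.86) and Cxcl2 (3.88), Galnt3 (3.63), Saa3 (3.56), Ccl20 (3.48), Acap1 (3.01), Traf1 (2.87), Upp1 (2.81), Rbms3 (2.77), Nostrin (2.74) and Tmem51 (2.67), all as log2 differences. They include Galnt3, an enzyme of mucin-type O-glycosylation, the acute-phase gene Saa3 and Upp1, which encodes a uridine phosphorylase. Their adjusted p-values ranged from 3.6e-05 for Acap1 to 0.0030 for Ccl20. Without HML2 replicate 1 the differences were 3.98 for Lcn2, 3.15 for Cxcl2 and 2.72 for Ccl20. The 12 largest decreases were, after Col3a1, the ferritin receptor gene Scara5 (-5.02), Acta2 (-4.88), the collagen VI gene Col6a3 (-4.85), Angpt1 (-4.78), which encodes a ligand of the endothelial receptor Tie2, and Stox2 (-4.64). Next were Abi3bp (-4.63), Mxd4 (-4.52), Ptn (-4.37), the thrombospondin gene Thbs1 (-4.35), Pcbd1 (-4.19) and the immunoproteasome subunit gene Psmb8 (-4.09). Their adjusted p-values ranged from 2.0e-06 for Col6a3 to 1.5e-04 for Acta2. Several of these genes had a signal near background in the lower group, where bacterial control probe sets read 1.97 to 36.2. Parental Lcn2, Ccl20, Nostrin, Traf1 and Cxcl2 and HML2 Abi3bp, Angpt1, Thbs1 and Pcbd1 had means in that range, so their differences on the log2(signal + 50) scale understate the change. Their place in this order therefore depends on the offset.

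**Figure D2:**
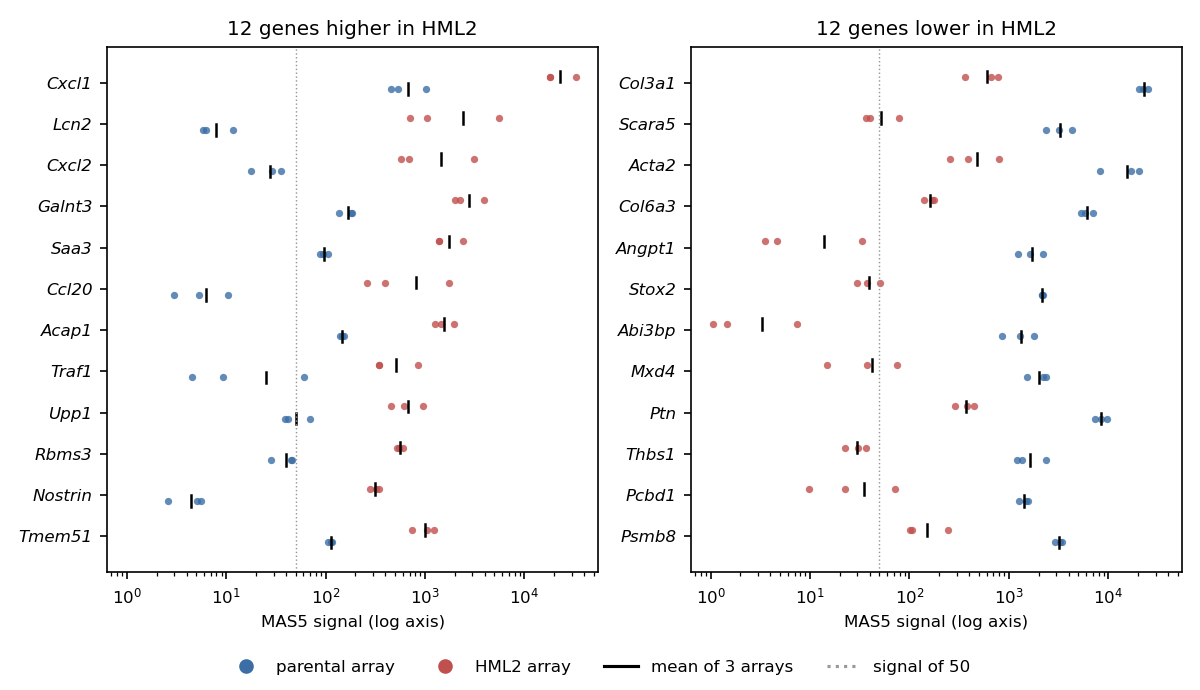
Signals of the 12 genes with the largest increase (left) and the 12 with the largest decrease (right) are shown on a log axis, with 1 point per array, blue for parental and red for HML2 cells, and a black bar at the mean of 3 arrays. No point of the HML2 group overlaps the parental group for any of these genes, and the dotted line marks the offset of 50.

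Targets of the transcription factor NF-kB were mostly higher in HML2 cells. Of 25 members tested, 20 were higher and 1, Ptges (-1.35), was lower (20 and 1 adjusted over the list alone), and the median log2 difference was 1.40. Besides Cxcl1, Lcn2, Cxcl2 and Saa3, the higher members included feedback inhibitors of the pathway, Nfkbia (1.26), Nfkbie (2.52) and Tnfaip3 (1.36), and the subunit genes Relb (1.33) and Nfkb2 (1.06). The list was called higher by camera with a preset correlation (adjusted p = 1.0e-09), and the call was lost at an adjusted p = 0.70 with an estimated correlation. Members of the list were higher on parental replicate 1 than on the mean of the other parental arrays, by a median of 0.37. HML2 replicate 1 stood further apart, with members higher on it than on the mean of the other HML2 arrays by a median of 0.89. Without that array the median was 1.12, and 20 members were still higher.

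Among 16 chemokine, cytokine and colony-stimulating factor genes tested, 5 were higher and 2 lower (7 and 2 adjusted over the list alone). The higher members were Cxcl1, Cxcl2, Ccl20, Cxcl3 (2.58) and Ccl2 (2.55), and the lower members were Tgfb2 (-1.81) and Il18 (-0.92). Il6 had a log2 difference of 0.82 that did not pass the test (adjusted p = 0.18). As a set the list was not called (camera adjusted p = 0.058). It was called at 0.0037 with the replicate number as a block and at 0.011 without parental replicate 1, both with the preset correlation. With an estimated correlation on all arrays its adjusted p was 0.77. On parental replicate 1 its members were higher than on the mean of the other parental arrays by a median of 0.41. They were higher on HML2 replicate 1 than on the mean of the other HML2 arrays by a median of 1.16. Without that array the list median was 0.55 with an adjusted p of 0.0499, against 1.25 on all arrays.

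The list for the unfolded protein response and targets of ATF4, the transcription factor of the amino acid response, had 12 higher and 3 lower genes among 33 (12 and 3 adjusted over the list alone), with a median of 0.31. The largest increases were in Trib3 (1.68), Psph (1.27), Sars (1.03) and Slc7a5 (0.99). Psph acts in serine synthesis, Sars charges transfer RNA with serine and Slc7a5 is part of an amino acid transporter, whereas the lower members Dnajb9 (-0.68), Pdia6 (-0.64) and Dnajc3 (-0.59) encode chaperones and a disulfide isomerase of the endoplasmic reticulum. The list was called higher (camera adjusted p = 0.019), but not with quantile normalization (0.060) or an estimated correlation (adjusted p = 0.77). Its members were higher on HML2 replicate 1 than on the mean of the other HML2 arrays by a median of 0.50, and without that array the list median was 0.15, still called (adjusted p = 0.042). Trib3 had a difference of 1.05 without that array, and its call was lost when any parental array or HML2 replicate 3 was left out. The call of Sars was lost without parental replicate 2 or parental replicate 3.

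Genes of the extracellular matrix were mostly lower in HML2 cells: 13 of 19 tested were lower and 3 higher (3 and 14 higher and lower when adjusted over the list alone), with a median log2 difference of -0.78. Col3a1, all 3 collagen VI genes tested, including Col6a2 (3279.8 ± 249 against 329 ± 38.8), and Thbs1 had the largest decreases, and Nid1 (1.61), Lama5 (0.94) and Lamb1 (0.40) were higher. Among 25 genes of the TGF-beta response, 12 were lower and 1, Junb (1.00), was higher (1 and 14 adjusted over the list alone). Tgfbi (-3.53), the latent TGF-beta binding protein gene Ltbp3 (-2.19) and Fstl1 (-1.84) fell, as did the receptor genes Tgfbr1 (-0.63) and Tgfbr2 (-0.50), and the median of that list was -0.64, or -1.06 without parental replicate 1. The mesenchymal list had 9 lower genes and 1 higher, Tgfb1 (0.94), among 17 (1 and 10 adjusted over the list alone). Sparc (-2.12), S100a4 (-1.98) and the gelatinase gene Mmp2 (-1.76) followed Acta2 in size, and the transcription factor genes Prrx1 (-1.17) and Twist2 (-0.71) were also lower. The intermediate filament gene Vim (-0.15) and other transcription factor genes, Zeb1 (-0.02), Zeb2 (-0.19), Snai2 (-0.22) and Twist1 (0.15), did not pass the test.

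These 3 lists were called lower by camera, with adjusted p-values of 6.0e-05 for matrix, 6.0e-05 for the TGF-beta response and 6.5e-04 for mesenchymal genes. With an estimated correlation the calls were lost, at an adjusted p = 0.58, 0.37 and 0.51 in that order. Of 5 basal and myoepithelial genes tested, 4 were lower and 0 higher (0 and 4 higher and lower when adjusted over the list alone): Acta2, the myosin kinase gene Mylk (-1.74), Foxc1 (-1.51) and Egfr (-1.23). That list was called lower (adjusted p = 0.0026), again not with an estimated correlation (adjusted p = 0.37).

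Cytoskeleton and motility genes went both ways, with 7 higher and 8 lower of 30 (7 and 8 adjusted over the list alone). The myosin light chain gene Myl9 (-3.55) and Rnd3 (-2.03) were lower and Rnd1 (1.70) was higher, and the list was not called (adjusted p = 0.74). Rnd1 had a difference of 1.12 without HML2 replicate 1, and its call was lost without parental replicate 2 or parental replicate 3. Matrix proteases and their inhibitors had 7 higher and 2 lower genes of 22 (8 and 3 adjusted over the list alone). Mmp10 (2.04), the urokinase receptor gene Plaur (1.55) and Mmp9 (1.50) were higher, Mmp2 was lower, and this list was not called either (adjusted p = 0.20). S100 and annexin genes numbered 2 higher and 4 lower of 17 (2 and 5 adjusted over the list alone), without a call (adjusted p = 0.19). They included S100a4, S100a8 (-1.62) and S100a13 (-1.01), which were lower, and Anxa7 (0.87), which was higher. S100a8 had a difference of -0.99 without parental replicate 1, and its call was lost without that array, parental replicate 3, HML2 replicate 2 or HML2 replicate 3.

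**Figure D3:**
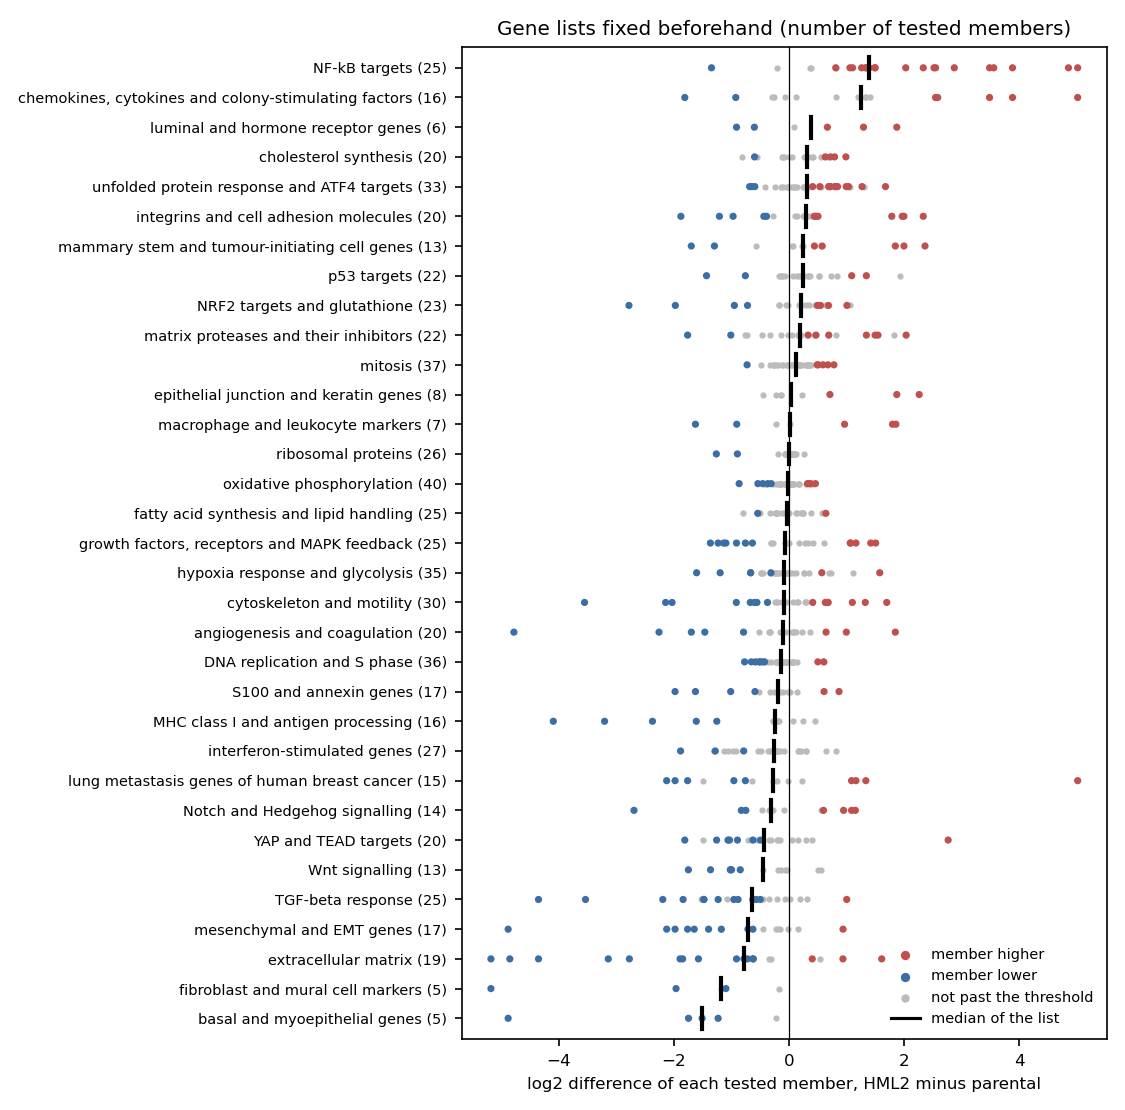
Each row is 1 of 33 gene lists with its number of tested members, ordered by median, and each point is the log2 difference of a member, HML2 minus parental. Red and blue points are members higher or lower in HML2 cells, grey points did not pass the threshold and the black bar is the list median, which is highest for NF-kB targets (1.40) and lowest for basal and myoepithelial genes (-1.51).

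Some genes of the immunoproteasome and of the peptide transporter that loads MHC class I molecules were lower in HML2 cells. Psmb8 went from 3202 ± 255 to 149.8 ± 80.8, Psmb9, another immunoproteasome subunit gene, from 1308 ± 349.7 to 103 ± 61.6, and the peptide transporter gene Tap1 from 826 ± 131 to 138 ± 115. Tap2 (-1.61) and Nlrc5 (-1.25), which encodes a transactivator of MHC class I genes, completed the 5 lower members of 16, with 0 higher (0 and 5 higher and lower when adjusted over the list alone). Psmb10 (0.25), also an immunoproteasome subunit gene, and Psme1 (-0.20), a proteasome activator gene, did not pass the test. The class I heavy chain genes H2-K1 (-0.28) and H2-D1 (-0.27) and the light chain gene B2m (-0.17) did not pass it either. The list was called lower (camera adjusted p = 0.019), though not with an estimated correlation (adjusted p = 0.70). Its members were higher on HML2 replicate 1 than on the mean of the other HML2 arrays by a median of 0.54, and the list median was -0.24 on all arrays and -0.38 without that array.

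Of 27 interferon-stimulated genes, 0 were higher and 3 lower (0 and 3 higher and lower when adjusted over the list alone), namely Ifit2 (-1.88), Trim30a (-1.28) and Dtx3l (-0.79), and the list was not called (adjusted p = 0.30). The call of Dtx3l was lost without parental replicate 1 or 3 or HML2 replicate 2 or 3. Replicate 1 stood apart in both groups: members of this list were higher on it than on the mean of the other arrays of the group, by a median of 1.18 for HML2 and 0.98 for parental cells. The list median was -0.26 on all arrays, -0.77 without HML2 replicate 1, when the list was called lower (adjusted p = 0.0089), and 0.14 without parental replicate 1, when it was not called (adjusted p = 0.89). With the replicate number as a block the median was -0.26 and the list was not called (adjusted p = 0.069). Relative to the parental mean, the list median was lower on the HML2 array than on the parental array of each number. The values were 0.44 against 0.65 for replicate 1, -0.73 against -0.59 for replicate 2 and -0.84 against -0.19 for replicate 3. The positive median arose when HML2 replicate 1, where members were high, was left without the parental array of its number.

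Epithelial junction and keratin genes were tested for 8 members, of which 3 were higher and 0 lower (3 and 0 higher and lower when adjusted over the list alone). These were the membrane protease gene St14 (2.26), the keratin gene Krt8 (1095 ± 60.3 against 4175 ± 649.8) and Pkp3 (0.71), while Epcam had a difference of -0.45 that did not pass the test. Without HML2 replicate 1 the difference of St14 was 1.68, and the call of Pkp3 was lost without any array but parental replicate 3. Luminal and hormone receptor genes had 3 higher and 2 lower of 6 (3 and 2 adjusted over the list alone), with Krt8, Foxa1 (1.30) and Tbx3 (0.67) higher and the oestrogen receptor gene Esr1 (-0.91) and Tff1 (-0.60) lower. The call of Tbx3 was lost without parental replicate 1 or 3 or HML2 replicate 2 or 3. In the mammary stem and tumour-initiating cell list, 5 genes were higher and 2 lower of 13 (6 and 3 adjusted over the list alone). The efflux transporter gene Abcb1b (2.36), the integrin gene Itga6 (2.00) and Procr (1.85) were higher, whereas another transporter gene, Abcg2 (-1.70), was lower. Integrins and adhesion molecules had 7 higher and 5 lower genes of 20 (7 and 5 adjusted over the list alone), among them Icam1 (2.33), Itga6 and Pvr (1.97), which were higher, and Mcam (-1.88), which was lower. Pvr had a difference of 1.26 without HML2 replicate 1, and its call was lost without parental replicate 2 or parental replicate 3. None of these lists was called (adjusted p = 0.29, 0.32, 0.089 and 0.24 in that order). The stem cell list was called at 0.048 without parental replicate 1.

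Genes linked to lung metastasis of human breast cancer did not move in a common direction: 4 were higher and 5 lower of 15 (4 and 5 adjusted over the list alone; camera adjusted p = 0.37). Cxcl1 was higher, and Sparc, S100a4 and Mmp2 were lower. Growth factor, receptor and MAPK feedback genes had 5 higher and 7 lower members of 25 (5 and 9 adjusted over the list alone), without a call (adjusted p = 0.78). The hepatocyte growth factor receptor gene Met (1648 ± 131 against 4771 ± 315) and the phosphatase gene Dusp5 (1.42; 1.15 and not called without parental replicate 3) were higher, and Btc (-1.36) and Egfr were lower. Angiogenesis and coagulation genes had 3 higher and 5 lower of 20 (3 and 7 adjusted over the list alone) and no call (adjusted p = 0.36). Angpt1, Sema3a (-2.26) and the lymphatic growth factor gene Vegfd (-1.69) were lower, and Procr was higher.

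Wnt signalling genes had 6 lower and 0 higher members of 13 (1 and 6 higher and lower when their p-values were adjusted over the list alone), with the receptor gene Fzd2 (-1.75), Tcf7l2 (-1.36), Wnt5a (-1.02) and Lgr4 (-1.01) as the largest. The call (camera adjusted p = 0.033, median -0.45) was lost at 0.058 without HML2 replicate 3, with a median of -0.30, at 0.051 with the replicate block, at 0.0998 with a minimum signal of 250 and at 0.65 without a signal filter. It was also lost at an adjusted p = 0.70 with an estimated correlation. In the Notch and Hedgehog list 4 genes were higher and 3 lower of 14 (5 and 6 adjusted over the list alone; camera adjusted p = 0.56). The Hedgehog effector gene Gli2 (-2.69) was lower, and Dhh (1.15), Jag1 (1.09) and Ptch1 (0.95) were higher. Jag1 had a difference of 0.69 without HML2 replicate 1, its call was lost without any of the parental arrays, and that of Dhh without parental replicate 2 or 3 or HML2 replicate 3. YAP and TEAD targets had 1 higher gene, Rbms3, and 7 lower of 20 (1 and 8 adjusted over the list alone), including Tgfb2, Nt5e (-1.26) and Asap1 (-1.06). That list was not called (adjusted p = 0.059), but was called lower without parental replicate 1 (0.0089), without HML2 replicate 1 (0.033), without a signal filter (0.022) and with median centring (0.040).

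Of 36 DNA replication and S phase genes, 2 were higher and 7 lower (2 and 7 adjusted over the list alone), with Cdc45 (-0.77), Chaf1b (-0.65) and the helicase gene Mcm4 (-0.58) lower and Gins3 (0.60) higher. Of 37 mitosis genes, 5 were higher, including Ect2 (0.78), Cenpe (0.68) and Mad2l1 (0.59), and 1, Nuf2 (-0.73), was lower (4 and 1 adjusted over the list alone). Neither list was called (adjusted p = 0.21 and 0.21). Both depended on the arrays used. Mitosis genes were lower on HML2 replicate 1 than on the mean of the other HML2 arrays by a median of 0.55, and the median of the list was 0.12 on all arrays, 0.36 without HML2 replicate 1, when it was called higher (adjusted p = 9.6e-04), and -0.037 without HML2 replicate 2. The median of the S phase list was -0.13 on all arrays, -0.23 without parental replicate 1, when it was called lower (adjusted p = 0.030), and 0.015 without HML2 replicate 1. Replicate 1 was low in both groups. Its median difference from the other parental arrays was -0.29 for mitosis and -0.26 for S phase, and -0.36 for S phase among HML2 arrays. Leaving it out of 1 group thus unbalances the comparison. With the replicate number as a block neither list was called (camera adjusted p = 0.097 for each). Leaving out parental replicate 3 ended the calls of Cdc45, Chaf1b, Mcm4, Gins3, Cenpe and Nuf2, and other single arrays those of Chaf1b, Mcm4, Gins3 and Cenpe. The p53 target list had 2 higher genes, the cell cycle inhibitor gene Cdkn1a (1.34) and Rrm2b (1.09), and 2 lower, Sesn1 (-1.43) and Phlda3 (-0.76), of 22 (2 and 2 adjusted over the list alone; camera adjusted p = 0.24). Both increases were largest on HML2 replicate 1 and were 0.81 and 0.68 without it. The calls of Cdkn1a and Rrm2b were lost without any of the parental arrays (adjusted p up to 0.12 and 0.11), that of Rrm2b also without HML2 replicate 3, and both with no signal filter.

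Among metabolic lists, cholesterol synthesis had 4 higher genes, Msmo1 (0.99), Fdps (0.79), Cyp51 (0.72) and Ebp (0.63), and 1 lower, Nsdhl (-0.60), of 20 (5 and 2 adjusted over the list alone). It was not called (adjusted p = 0.17) except without parental replicate 1 (0.0089) or HML2 replicate 1 (0.030). Hypoxia response and glycolysis genes had 2 higher and 5 lower of 35 (2 and 3 adjusted over the list alone). The glucose transporter gene Slc2a3 (1.58) was higher, and Bnip3 (-1.60), the prolyl hydroxylase gene P4ha2 (-1.20) and Pdk1 (-0.67) were lower. Fatty acid and lipid genes had 1 higher gene, Pnpla2 (0.64), and 1 lower, Dgat1 (-0.54), of 25 (0 and 0 adjusted over the list alone). Oxidative phosphorylation genes had 4 higher, including Ndufa9 (0.46), and 5 lower, including Ndufb3 (-0.86), Atp5o (-0.54) and Ndufs1 (-0.46), of 40 (3 and 4 adjusted over the list alone). NRF2 and glutathione genes had 4 higher and 4 lower of 23 (4 and 4 adjusted over the list alone), among them the glutathione transferase genes Gstm2 (-2.78), Gstm1 (-1.97) and Gsta4 (-0.95), which were lower, and Hmox1 (1.01), which was higher. Ribosomal protein genes had 0 higher and 2 lower, Rpl14 (-1.26) and Rps6 (-0.90), of 26 (0 and 2 higher and lower when adjusted over the list alone). These lists were not called (adjusted p = 0.56, 0.98, 0.92, 0.30 and 0.90 in that order). Leaving out parental replicate 3 ended the calls of Fdps, Cyp51, Ebp, Pdk1, Pnpla2, Dgat1, Ndufs1 and Hmox1, and leaving out other single arrays those of Cyp51, Ebp, Pnpla2, Dgat1 and Ndufs1.

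A population recovered from lung could hold cells of other types. Of 22 lung epithelium markers, 4 had a mean signal of at least 100 in HML2 and 3 in parental cells, of 33 macrophage and leukocyte markers 7 and 6 did, and of 28 endothelial markers 5 and 4 did. Of the 4 lung epithelium markers tested, Emp2 was lower (-1.96), while Sftpb, a surfactant protein gene (0.34; mean signals of 83.2 in parental and 120.3 in HML2 cells), Hopx (0.01) and Lyz1 (-0.66; called at -0.90 without HML2 replicate 1) did not pass the test, so 0 were higher and 1 lower (0 and 1 adjusted over the list alone). Of 7 leukocyte markers tested, Laptm5 (311 ± 76.3 against 1191 ± 116), Itgb2 (1.86) and Cd14 (0.97) were the 3 higher, and S100a8 and Lyz2 (-0.91) the 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.43). The pan-leukocyte gene Ptprc had mean signals of 5.24 in parental and 8.71 in HML2 cells. Of 4 endothelial markers tested, Ramp2 (1.25) was higher and Calcrl (-1.98) lower (1 and 1 adjusted over the list alone), and Eng (-0.35) and Egfl7 (-0.44) did not pass. Icam2 was below the filter, with 6.39 ± 1.50 in parental and 177 ± 72.2 in HML2 cells. Calcrl had a difference of -2.58 without HML2 replicate 1, and its call was lost without parental replicate 1, parental replicate 3 or HML2 replicate 3. Fibroblast and mural cell markers had 3 lower, Col3a1, Rgs5 (-1.96) and Pdgfra (-1.09), and 0 higher of 5 (0 and 4 higher and lower when adjusted over the list alone), and Gsn (-0.18) did not pass. That list was called lower (adjusted p = 0.0041), but not with an estimated correlation (adjusted p = 0.58) or without a signal filter (0.098). Of 2 adipocyte and muscle markers tested, the creatine kinase gene Ckm (1227 ± 223 against 169.5 ± 33.6) was lower and Acta1 (-0.32) did not pass (0 and 1 higher and lower when adjusted over the list alone). Mylpf was below the filter, with 82.8 ± 22 in parental and 79.7 ± 16.4 in HML2 cells. Of 3 sex-chromosome identity genes tested, Kdm5c (0.71) was higher, although another of its probe sets was called in the opposite direction and the call was lost without any array but HML2 replicate 2, and Eif2s3x (0.09) and Kdm6a (-0.23) did not pass (1 and 0 adjusted over the list alone). Lists with under 5 tested members were not tested as sets.

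The ratio of 3' to 5' signal, a measure of RNA integrity, differed by -0.017 on the log2 scale for Gapdh (exact permutation p = 0.7, two-sided) and by -0.086 for beta-actin (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Of 6 ratios among the 3', middle and 5' probe sets of these genes, 4 parted the groups without overlap, with differences of at most 0.097. The first principal component took 67.7% of the variance and separated the groups, and the second took 20.5%. HML2 replicate 1 stood apart from the other arrays of its group, with an SD of gene-wise log2 differences from them of 0.495, against 0.217 to 0.325 for the other 5 arrays within their groups. The set test also called 1 to 15 lists in the other divisions of the 6 arrays into 3 and 3, against 9 in the real grouping. In the other divisions limma called 0 genes at an adjusted p below 0.05 and 16 to 901 genes at an unadjusted p below 0.05, against 2550 and 3670.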

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

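These values come from probe sets that the comparison of genes did not use, and they were examined after the main results were seen. Among 19 mouse control probe sets, 5 had a mean signal of at least 100 and no overlap between the HML2 and parental arrays, which chance gives for 10% of probe sets. The groups did not overlap for 4155 of the 9361 genes tested, a larger share, so the control probe sets were not unusual in this. In 4 of the 5 probe sets the HML2 arrays were higher and in 1 lower. The probe set for the middle of the Gapdh transcript had a mean signal of 26540.1 ± 1354 (SD, n = 3) in HML2 and 22627 ± 1615 in parental cells. A control for the B1 family of repeats read 15405 ± 3716 against 8256 ± 1604, and a control for the B2 family read 1967 ± 125 against 1165 ± 94.7, although another B2 control differed by 0.050 on the log2 scale. The 3' probe set of the transferrin receptor control read 237 ± 64.7 against 136 ± 10.0. The 3' probe set of the pyruvate carboxylase control was the lower one, with 95.4 ± 23 in HML2 against 373 ± 75.8 in parental cells.

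Of 1947 probe sets that passed the signal filter but had no single gene name, 144 were called higher and 202 lower in HML2 cells (limma, adjusted p below 0.05). Their genes were not identified here, and no explanation was tested for these values or for the control probe sets. The search for a single array far from the rest of its group needs at least 4 arrays and was not applied to groups of 3.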

How the results depend on the processing

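The alternatives were fixed before the data were examined, except leaving out 2 chromosomes and combining the estimated correlation with the replicate block, which were chosen after seeing the data. In alternatives that give 1 value per gene, none of the 134 tested genes selected by the naming rule was called in the opposite direction. No list called in the report was either. Genes named outside the rule were not followed through the alternatives, except NF-kB targets without HML2 replicate 1. When every probe set was tested, Kdm5c had probe sets called in both directions. Of the 134 genes, 101 stayed on the same side of the threshold throughout, and most losses came from leaving out an array (28 without parental replicate 3). Against 1155 higher and 1395 lower genes (270 and 502 at least 2-fold), array weights gave 2422 and 2631, and testing every probe set gave 1971 and 2483 (484 and 915 at least 2-fold), the latter because 18359 probe sets were tested. An offset of 200 shrank the differences by construction and gave 141 and 276 genes at least 2-fold changed. Leaving out each array gave 590 to 1577 higher and 795 to 1845 lower genes, lowest without parental replicate 3 and highest without HML2 replicate 1, and 218 to 322 higher and 464 to 554 lower genes at least 2-fold changed. Without HML2 replicate 3 there were 715 higher and 956 lower genes. With the replicate number as a block there were 1670 higher and 1831 lower genes (296 and 518 at least 2-fold), the chemokine list became called (0.0037) and the Wnt list was lost (0.051). The block changed no other list call and ended the call of none of the 134 genes. Median centring shifted the median of all genes from -0.019 to 0.040 and made 53.5% of called genes higher, against 45.3%. Using the mean of a gene's probe sets, 4 genes were called in the opposite direction, and without probe sets of shared sequence 6 were, since another probe set then stood for the gene. Without the 2 chromosomes there were 1107 higher and 1067 lower genes.

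The 9 list calls were all lost with an estimated correlation, with adjusted p-values from 0.37 to 0.77, and with the block added they lay between 0.60 and 0.67. Leaving out an array ended the call of the Wnt list alone. The list also lost its call without a filter (0.65) and with a minimum of 250 (0.0998), the fibroblast list without a filter (0.098) and the list of ATF4 targets with quantile normalization (0.060). The cause was not tested. The chemokine list became called with no offset (0.040), no filter (0.023), a minimum of 250 (0.025) and without HML2 replicate 2 (0.019) or HML2 replicate 3 (0.025), besides the settings given in the report. With no filter its median was only 0.14, against 1.25 in the main comparison. For the Gapdh control the middle-to-5' ratio differed by 0.080 and the 3'-to-middle ratio by -0.097 (both exact permutation p = 0.1), against -0.017 for 3' to 5'. For beta-actin the middle-to-5' ratio differed by -0.063 (exact permutation p = 0.1) and the 3'-to-middle ratio by -0.022 (exact permutation p = 0.7). Signal over background limits what can be said of genes in the range of the bacterial controls, up to 36.2, where differences have no reliable size.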

Other observations

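The tests in this part were chosen after the results they bear on had been seen, except the regroupings of the arrays, which were set out beforehand. Genes of 2 chromosomes were lower as a whole in HML2 cells, a pattern not asked for by the design. On the chromosome that carries Ranbp1, Naa50 and Hmgn1, the median log2 difference of 302 tested genes was -0.42, and 85.8% of them lay below 0. On the chromosome that carries Rpl37a, Ncl and Hnrnpu, the median of 521 genes was -0.32, and 77.7% lay below 0. The decrease was spread along both: all 27 and all 49 overlapping windows of 40 neighbouring genes had medians below 0. Neighbouring windows share most of their genes, so these counts are not independent. All 3 HML2 arrays showed it, with medians of -0.39, -0.43 and -0.44 for the first and -0.28, -0.35 and -0.34 for the second. A stretch of another chromosome, that of Slc25a5, Rps4x and Pgk1, was lower still: 4 overlapping windows, from the one that starts at Hprt to the one that ends at Gspt2, had medians from -0.89 to -0.63, whereas the median of that chromosome as a whole was -0.049. No explanation was tested for that stretch. Together the first 2 chromosomes held 8.81% of the genes tested but 305 of the 1395 lower genes (21.9%).

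Smaller increases covered the chromosome of Rps3a1, S100a6 and H2az1 (median 0.20, 451 genes) and that of Rps7, Rps29 and Hsp90aa1 (0.15, 332 genes). In 10000 permutations of genes over chromosomes, these 4 had p = 0.0001, the smallest the permutations can give. The chromosomes of Snx17, Rplp0 and Actb (median 0.068) and of Serbp1, Tmsb10 and Ybx3 (0.094) had the same p. This p therefore does not part large from small shifts. In all, 8 of 20 chromosomes passed an adjusted p of 0.05. Genes are not independent, so these p-values are descriptive. The largest absolute chromosome median was 0.416 in the real grouping and at most 0.160 in the other divisions of the arrays.

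For the lower medians of these 2 chromosomes, probe brightness was tested as a technical explanation and fewer chromosome copies as a biological one. In 1000 gene sets matched on brightness, the lowest median was -0.109 for the first chromosome and -0.086 for the second, so brightness does not account for medians of -0.42 and -0.32. Fewer copies in the HML2 population would lower all brightness classes, though dim genes less on the log2(signal + 50) scale. The medians of the dim, middle and bright classes were -0.51, -0.39 and -0.39 on the first chromosome. They were -0.31, -0.41 and -0.262 on the second. The dim class of the first chromosome thus fell most. The chromosomes were picked for low medians, so low medians of their classes were nearly given and cannot decide the question. A reduced copy number of these chromosomes in the HML2 population may underlie the shift. This is a hypothesis: copy number was not measured, the bound was set after the values were seen, and selection in the lung cannot be separated from drift during passage in a population of this kind.

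For the increase of NF-kB targets, leukocytes of the host carried into the culture and an increase in HML2 replicate 1 alone were tested. The test took leukocytes to bring their own markers, which would then rise, each on its own probe set, at least as far as the NF-kB targets (median 1.40). The 33 macrophage and leukocyte markers had a median log2 difference of 0.016 (SD 0.63), and 16 of them, Ptprc among them, had HML2 means within the range of the bacterial controls. The list mixes T cell, B cell and macrophage genes, so macrophages alone could leave its median near 0. Within that limit the median argues against a mixture of leukocytes as the source of the whole increase. Of the 7 markers bright enough to be tested, Laptm5, Itgb2 and Cd14 were higher and Lyz2 and S100a8 lower, with a median of 0.020 and an SD of 1.33, so a small share of leukocytes behind part of it stays open. Without HML2 replicate 1 the median of the list was 1.12 with 20 members higher (adjusted p = 1.2e-08 with the preset correlation; on all arrays the call was lost at 0.70 with an estimated one), so that array alone does not account for it. Culture conditions such as density, which the labels do not give for each dish, and a difference between the tumour cell populations stay open as well and were not tested.

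For the decrease of matrix genes, fibroblasts in the parental culture and the 2 lower chromosomes, on which Col3a1 and Col6a3 lie, were tested. By the same reasoning fibroblast and mural cell markers would fall at least as far as the matrix genes (median -0.78). The 23 markers that are not on the matrix list had a median of -0.16 with an SD of 0.63, a gap just under the spread, and leaving out Col3a1 alone, the only marker tested within that list, 27 had a median of -0.18 with an SD of 0.59, a gap just over it. Dcn and Lum were among 12 of all 28 markers with parental means within the range of the bacterial controls, which speaks against many fibroblasts. Rgs5 and Pdgfra, which are not on the matrix list, were called lower, which goes with them. So does the median of -1.18 (SD 1.93) of the 5 markers bright enough to be tested, Col3a1 among them. As the outcome turns on which markers are used, and dim markers cannot show a large fall, this explanation stays open. Without genes of the 2 chromosomes the matrix list had a median of -0.75, against -0.78 with them. It was still called with the preset correlation (camera adjusted p = 9.2e-04, against 6.0e-05 with all genes). With all genes the call was lost at 0.58 with an estimated correlation. By these medians the 2 chromosomes do not account for the whole decrease. A median hardly registers the size of the largest falls, so the part carried by Col3a1 and Col6a3 was not measured. For leukocytes and fibroblasts the test given here replaced earlier forms: a test on signal levels of a few transcripts, which set probe sets against each other and argued against both, a count of markers whose groups did not overlap, which left both open, and, for fibroblasts, the median with Col3a1 included, which left them open. A difference between the tumour cell populations themselves, whether gained by selection or present in a subset of parental cells, stays open and was not tested.

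With 10 divisions of 6 arrays into 3 and 3, no share under 0.05 can be reached. The real grouping gave 2550 called genes and the highest other grouping 0, so 1 of the 10 gave as many, and for genes changed at least 2-fold the values were 772 and 0. In the other groupings the real difference adds to the spread within groups, which lowers their counts. For gene lists the picture differed: 9 were called in the real grouping, but 5 of the 10 groupings called as many and the highest other called 15, for parental 1, HML2 1 and HML2 2 against the rest. Among the 3 other groupings that part every same-numbered pair, as the real one does, 1, 5 and 10 lists were called, whereas the remaining groupings part 1 pair. The NF-kB list reached an absolute median of 1.02 and an adjusted p of 2.0e-09 in other groupings, against 1.40 and 1.0e-09. Of the 9 called lists, all but the MHC class I list (0.24 against 0.39 in another grouping) had their largest absolute median in the real grouping. Each other grouping sets 2 HML2 arrays against 1 and so keeps part of the real difference, and how much of its list calls comes from that was not tested.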
